A study of Mus musculus with 2 samples.

How the data were processed

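RNA of mouse fibro/adipogenic progenitors was sequenced after 24 h with 1 µM recombinant Musclin or with vehicle, and the table compared here holds 2 samples, 1 per group. The Musclin column was matched to its sample by name. The other column carries the code BSA, and it was taken as the vehicle sample because the series has no further sample. No label says that the vehicle was BSA, so every direction reported rests on that assignment. Whether a column stands for 1 culture or for several pooled cultures is not given in the sources used here.

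The deposited table lists 88702 transcripts of 30491 genes with Ensembl identifiers. Expression is given per transcript in FPKM (fragments scaled to transcript length and to library size), per the file headers, with 1 value per condition. The authors also deposited a fold change per transcript, which equals the ratio of both FPKM values with a zero replaced by 0.0001, and the deposited log2 column is the log2 of that fold. The p-value and q-value columns are the authors' own, and the test behind them is not given in the sources used here. At the smallest p-value the deposited q-value is 22426 times the p-value, as a Benjamini-Hochberg adjustment over that many transcripts would give. The adjustment was not recomputed over the whole column. Of all transcripts, 66357 have a p-value of 1. Transcripts marked significant by the authors all have a fold of 2 or more in either direction, and the largest deposited q-value among them is 0.0021. No transcript with such a fold and a deposited q-value under 0.05 is left unmarked. The q-value bound the authors used cannot be read from these values. The submitters' processing notes name StringTie, DESeq2 and edgeR as tools the authors used, without roles or versions. The aligner and the genome build are not given in the sources used here. Of 88029 transcripts found in the GENCODE vM21 annotation of GRCm38, 87772 have the same start and end there, and coordinates are therefore printed as GRCm38 positions.

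Depth was worked out from the deposited FPKM values. In single-exon genes with 1 listed transcript, FPKM times transcript length came in steps that stand for 1 aligned base. In 2491 such genes of the Musclin library 72.1% of the values were whole numbers of bases within 0.1, and in 2521 of the vehicle library 72.4% were. The steps correspond to 6.69 Gb (gigabases) of aligned sequence with Musclin and 6.76 Gb with vehicle, and the commonest totals were 149 and 298 bases, taken as a read and a read pair. Dividing by 298 gave 22457073 and 22677272 fragment equivalents, and the transcripts of the table hold 97.1% and 97.0% of the aligned bases.

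Gene values are the FPKM summed over a gene's transcripts. Log2 ratios are of Musclin over vehicle on FPKM plus a pseudocount of 1, a scale that understates differences of low genes. Genes with at least 1 FPKM in either library were kept. A gene was counted as higher or lower at 2-fold or more on that scale. With 1 library per group no test was run. A 95% exact Clopper-Pearson interval was computed for the ratio of fragment equivalents per gene, and it covers counting error only. It belongs to the ratio of aligned bases, which can differ from the ratio of summed FPKM where the listed transcripts of a gene differ in length.

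The comparison, the rule for named genes and 37 gene lists (805 entries, 764 symbols, of which 737 are in the table) were fixed before the data were examined. The lists come from textbook knowledge, except a list of 4 genes taken from what is known of the study. Named are the 12 genes with the highest and the 12 with the lowest log2 ratio among those with an official symbol and at least 5 FPKM in a library, the 4 study genes, and up to 4 members per list with the largest absolute log2 ratio at the same expression floor. Predicted genes and pseudogenes count in the totals and are not named, and some list members that the rule takes are not reported here. Any other gene named in the text was chosen after its values were seen. For the 33 lists with 3 or more measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on expression deciles, as a description of these libraries. The random range of a list is the central 95% of those medians.

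The procedure was tested on simulated data with counting noise alone, for 30422 genes of this comparison. Counts were drawn in units of 298 bases for every gene, however short. Of 12801 genes at the expression floor, 53 without a simulated difference passed the 2-fold rule. Of 100 genes with a simulated 4-fold difference 93% passed in the right direction, against 8% of 100 genes with a simulated 2-fold difference, because the pseudocount shrinks the ratio (median absolute log2 of 0.88). Of 100 random lists 6 fell outside the central 95% of matched random-list medians. Alternatives were other pseudocounts, 2 other scalings, other expression floors, known symbols alone, lists without their largest member, protein-coding transcripts alone, aligned bases per gene, and single transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.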

Results

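Fibro/adipogenic progenitors (FAPs), the mesenchymal stromal cells of skeletal muscle that can become fibroblasts or adipocytes, were sorted from wild-type mouse muscle and grown in serum-containing medium. Musclin is a secreted peptide encoded by Ostn that binds the natriuretic peptide clearance receptor, the product of Npr3. One set of cells received 1 µM recombinant Musclin and the other received vehicle, each for 24 h, and the RNA-seq comparison asks which transcripts differ early after Musclin is added. There is 1 library per group, so no difference has a replicate check and no p-value was computed. The depth was 6.69 Gb of aligned sequence (22457073 fragment equivalents) with Musclin and 6.76 Gb (22677272) with vehicle. The column read as vehicle is named BSA in the table and was assigned by elimination.

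Chemokine, matrix metalloproteinase and interferon-induced genes were among the highest in the Musclin library relative to vehicle, and members of the stress response list were among the lowest. Mmp10, which encodes a stromelysin, was listed at 23.4 FPKM with Musclin and 0.184 FPKM with vehicle. Cxcl5 and Cxcl1, which encode neutrophil attractants, were at 720 against 42.5 FPKM and 173 against 9.26 FPKM. At the other end, Car6, a carbonic anhydrase gene, was at 0.346 FPKM with Musclin and 16.9 FPKM with vehicle, and Cth, an enzyme of cysteine synthesis, at 1.66 against 31.3 FPKM.

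Of 12884 genes with at least 1 FPKM in either library, 220 were 2-fold or more higher with Musclin and 196 were 2-fold or more lower, while 96.8% lay within 2-fold. The median log2 ratio over these genes was -0.02, and the 5th to 95th percentile ran from -0.59 to 0.62. In a simulation with counting noise alone, 53 genes without a simulated difference passed the same rule, of 12801 at the expression floor. Of the 416 genes past 2-fold in the data, 413 had an aligned-base ratio whose 95% counting interval excluded 1. That interval covers counting error only and does not show that a ratio is past 2-fold. The counts depend on the pseudocount, with 400 higher and 360 lower at a pseudocount of 0.1 and 97 and 71 at a pseudocount of 5.

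**Figure D1:**
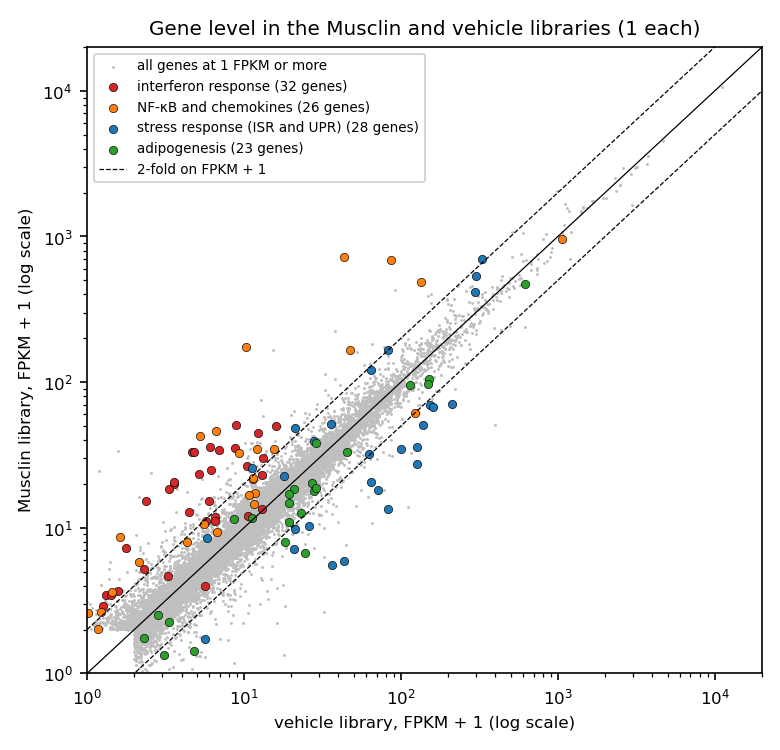
Each point is a gene, with its level in the vehicle library on the x axis and in the Musclin library on the y axis (both FPKM + 1, log scales), 1 library per group. The solid line marks equal levels and the dashed lines 2-fold. Members of the interferon (red) and NF-κB (orange) lists lie mostly above the equal line, and 17 of the 28 members of the stress response list (blue) lie below it.

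Among the 12 highest named genes, 3 metalloproteinase genes are neighbours on chromosome 9 (GRCm38), where Mmp13 spans 7272514 to 7283331, Mmp3 7445822 to 7455975 and Mmp10 7502352 to 7510240. Mmp3 was at 165 FPKM with Musclin and 14.2 FPKM with vehicle, and Mmp13, a collagenase gene, at 15.3 and 1.14 FPKM. The aligned-base ratio of Mmp10 was 127 (95% interval 63.1 to 326), resting on 905 fragment equivalents against 7. Cxcl5 (chromosome 5, 90759360 to 90761624) and Cxcl1 (90891241 to 90893115) had aligned-base ratios of 16.4 (15.6 to 17.3) and 16.5 (14.5 to 18.8). Ccl2, a monocyte attractant on chromosome 11 from 82035571 to 82037453, was at 693 FPKM with Musclin and 85.5 FPKM with vehicle. The cytokine gene Il6 was at 41.8 against 4.22 FPKM, the acute-phase gene Saa3 at 45.4 against 5.63 FPKM, and Penk, which encodes the enkephalin precursor, at 22.6 against 1.55 FPKM. The interferon-induced genes Ifit1 (32.3 against 3.64 FPKM), Zbp1 (32.1 against 3.79 FPKM) and Ifit3b (14.2 against 1.39 FPKM) complete the set. Ifit3b has a near-identical neighbour in Ifit3, so its share of the reads is uncertain.

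Among the 12 lowest named genes, Trib3, Chac1, Slc7a5 and Ddit3 belong to the stress response list. Slc7a5, a transporter of large neutral amino acids, was at 12.4 FPKM with Musclin and 81.4 FPKM with vehicle, an aligned-base ratio 6.57-fold lower (95% interval 6.14 to 7.03). The glycine transporter gene Slc6a9 was at 5.33 against 31.6 FPKM and Aldh1l2, an enzyme of mitochondrial folate metabolism, at 6.57 against 43.6 FPKM. Trib3, a pseudokinase gene, was at 4.91 against 42.7 FPKM, Chac1, whose product degrades glutathione, at 4.57 against 35.4 FPKM, and Ddit3, which encodes the stress transcription factor CHOP, at 26.2 against 126 FPKM. Gadd45a, a growth arrest and DNA damage gene, was at 9.77 against 64.7 FPKM. The aligned-base ratio of Car6 (chromosome 4, 150187015 to 150198470) was 48.8-fold lower (27.9 to 101) and that of Cth (chromosome 3, 157894248 to 157925077) 19.2-fold lower (14.9 to 24.9). The remaining genes were Car3, another carbonic anhydrase gene (1.21 against 15.3 FPKM), Avil, which encodes the actin-binding protein advillin (0.187 against 7.60 FPKM), and Ppef1, a protein phosphatase gene (0.698 against 6.86 FPKM).

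**Figure D2:**
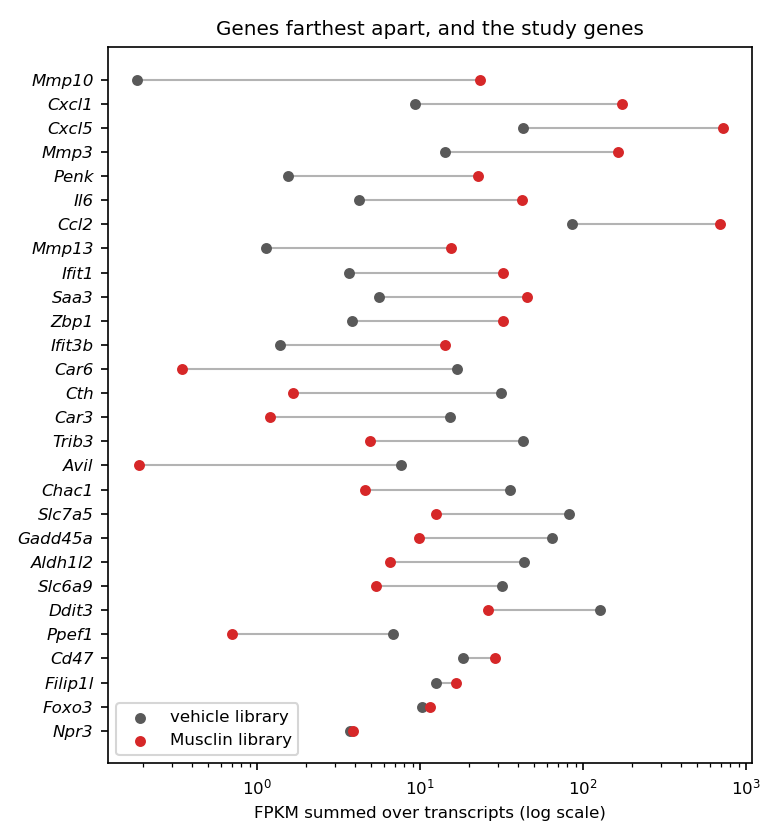
The 12 highest and 12 lowest genes by log2 ratio, among those with an official symbol and at least 5 FPKM in a library, and the 4 study genes, with FPKM summed over transcripts on a log x axis. Grey points are the vehicle library, red points the Musclin library, and the grey line joins both values of a gene. Mmp10 is at 23.4 FPKM with Musclin and 0.184 FPKM with vehicle, and the values of Npr3 (3.86 and 3.71 FPKM) nearly coincide.

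Inflammatory gene groups were higher with Musclin. Of 32 measured interferon-response genes, 24 were 2-fold or more higher, none was 2-fold lower and 8 lay between, with a median log2 ratio of 1.46. Isg15, a ubiquitin-like interferon effector gene, was at 35.1 FPKM with Musclin and 5.09 FPKM with vehicle. Of 26 measured NF-κB target and chemokine genes, 15 were 2-fold or more higher and 1 was 2-fold lower, with a median of 1.25. Both medians lay above those of all 10000 random lists, whose random range ended at 0.10 for the interferon list and at 0.13 for the NF-κB list. At a pseudocount of 5 the NF-κB median was 0.70. Members of the interferon list include close paralogs, the Ifit and Gbp families, whose reads can be divided among copies. Beside these groups, the leukocyte marker list had a median of 0.41 over 6 measured genes, above its random range, which ended at 0.31. Its summed FPKM over the 18 genes found in the table was 23.7 with Musclin and 23.8 with vehicle, and without Lyz2, the most abundant, 15.2 against 9.64 FPKM.

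The stress response list divided into members that were lower and members that were higher. Of 28 genes of the unfolded protein and integrated stress responses, 16 were 2-fold or more lower, 4 were 2-fold or more higher and 8 lay between. The median log2 ratio was -1.19, below all 10000 random lists, whose range began at -0.12. Trib3, Chac1, Slc7a5 and Ddit3 were the members farthest from 0. The 4 higher genes, named after their values were seen, were the endoplasmic reticulum chaperone and folding genes Calr (695 against 328 FPKM), Creld2 (24.9 against 10.2 FPKM), Manf (47.1 against 20.0 FPKM) and Pdia6 (164 against 81.4 FPKM). The list of NRF2 and oxidative stress genes had a median of -0.21, below its random range, which began at -0.14, with 1 gene of 20 2-fold higher and 2 lower. Within it Sqstm1, an autophagy receptor gene, was at 238 FPKM with Musclin and 615 FPKM with vehicle, and Slc7a11, the cystine transporter gene, at 8.77 and 20.2 FPKM. Sod2, mitochondrial superoxide dismutase, was at 19.0 against 8.69 FPKM and Nqo1, a quinone reductase gene, at 105 against 62.4 FPKM.

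Genes of glycolysis and of cholesterol synthesis were higher with Musclin. Of 25 measured hypoxia and glycolysis genes, 6 were 2-fold or more higher, none was 2-fold lower, and 24 had a log2 ratio above 0, with a median of 0.81. Slc16a3, a lactate exporter gene, was at 57.3 FPKM with Musclin and 12.3 FPKM with vehicle, Bnip3, a mitophagy receptor gene, at 62.8 against 19.7 FPKM, Egln3, an oxygen-sensing hydroxylase gene, at 9.12 against 2.59 FPKM, and Pdk1, a kinase that restrains pyruvate oxidation, at 12.1 against 3.72 FPKM. All 24 measured cholesterol synthesis genes had a log2 ratio above 0, 5 of them 2-fold or more, with a median of 0.73. Idi1 was at 20.7 against 7.12 FPKM, Fdps at 52.2 against 23.2 FPKM and Hsd17b7 at 28.3 against 12.9 FPKM. Both medians lay above all 10000 random lists.

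Adipocyte genes were lower with Musclin. Of 23 measured adipogenesis genes, 20 had a log2 ratio below 0 and 4 were 2-fold or more lower, none 2-fold higher, with a median of -0.46 that lay below all 10000 random lists. Cfd, which encodes adipsin, was at 5.74 FPKM with Musclin and 23.6 FPKM with vehicle, the adipokine gene Adipoq at 7.03 against 17.2 FPKM, the transcription factor gene Cebpa at 11.7 against 22.2 FPKM, and Lipe, hormone-sensitive lipase, at 9.94 against 18.2 FPKM.

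FAP marker genes went both ways. Of 26 measured genes of the FAP identity list, 4 were 2-fold or more higher and 1 was 2-fold lower, with a median of 0.15 just above a random range that ended at 0.13. That median was 0.09 without the expression floor and 0.13 without its largest member. Dcn, which encodes the proteoglycan decorin, was at 181 FPKM with Musclin and 64.8 FPKM with vehicle, Sema3c, a semaphorin gene, at 27.1 against 10.5 FPKM and the adhesion gene Vcam1 at 33.7 against 14.4 FPKM. The transcription factor gene Osr1 was at 15.1 against 34.8 FPKM, with an aligned-base ratio 1.60-fold lower (95% interval 1.45 to 1.77). Of 15 measured genes for secreted factors that act on muscle progenitors, 4 were 2-fold or more higher and 1 lower, with a median of 0.51, above all 10000 random lists. Besides Il6, which the NF-κB list also holds, the higher genes included the cytokine gene Lif (20.5 against 4.38 FPKM) and Fst, which encodes the myostatin antagonist follistatin (31.2 against 14.1 FPKM). Without the expression floor this median was 0.18, and without Il6 it was 0.35.

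Collagen and matrix genes as a group had a median log2 ratio near 0, while single members stood far apart. Of 44 measured collagen and matrix genes, 4 were 2-fold or more higher and 1 was lower, with a median of 0.03 inside the random range. Dcn, Tnc, which encodes tenascin C (387 against 148 FPKM), and P4ha2, a collagen prolyl hydroxylase gene (131 against 57.0 FPKM), were among the higher genes, and Col15a1 was at 2.88 against 8.47 FPKM. Of 20 measured matrix-degradation genes, 5 were 2-fold or more higher and 1 was lower, with a median of 0.03 and a mean of 0.49. The 3 metalloproteinase genes on chromosome 9 lead that list, and Mmp11 was at 15.3 against 60.5 FPKM. Of 20 TGF-β response genes 2 were 2-fold or more higher, with a median of 0.12, including Il11 (11.4 against 3.91 FPKM) and Inhba, the activin A gene (174 against 76.8 FPKM). None of 20 myofibroblast genes reached 2-fold, with a median of 0.03, and Tagln, a contractile protein gene, was at 228 against 299 FPKM.

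DNA replication genes were slightly lower with Musclin and mitotic genes were near their vehicle levels. Of 29 measured G1/S and replication genes, 22 had a log2 ratio below 0 and 2 were 2-fold or more lower, with a median of -0.27, below all 10000 random lists, whose range began at -0.13. Cdt1, a replication licensing gene, was at 11.6 FPKM with Musclin and 24.97 FPKM with vehicle, and Mcm2, which encodes part of the replicative helicase, at 23.0 against 47.8 FPKM. None of 31 G2/M genes reached 2-fold, and their median of 0.07 lay inside the random range. The mitotic gene Cenpa was at 14.6 against 8.95 FPKM and Mki67, a proliferation marker, at 35.1 against 26.0 FPKM. None of 13 genes for cyclin-dependent kinase inhibitors and related brakes reached 2-fold, with a median of 0.03, and Cdkn1a, which encodes p21, was at 162 against 102 FPKM. Of 24 immediate-early genes 1 was 2-fold higher, Ier3 at 161 against 51.3 FPKM, and 1 was 2-fold lower, with a median of -0.04 inside the random range.

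Genes that promote apoptosis were near their vehicle levels apart from Fas, the death receptor gene, at 11.9 FPKM with Musclin and 2.70 FPKM with vehicle. It was the 1 gene of 25 past 2-fold, and the list median of 0.07 lay inside the random range. Diablo, whose product antagonises apoptosis inhibitors, was at 11.7 against 17.9 FPKM, but the interval of its aligned-base ratio (0.822 to 1.02) included 1. Of 10 genes that inhibit apoptosis none reached 2-fold and 8 had a log2 ratio above 0, with a median of 0.28 above a random range that ended at 0.19. Birc3 was at 9.64 against 4.57 FPKM, the co-chaperone gene Bag3 at 56.2 against 31.3 FPKM and Cflar, a caspase-8 regulator, at 33.0 against 24.1 FPKM, and without Birc3 the median was 0.17. Of 23 p53 targets 1 was 2-fold higher and 2 were lower, with a median of 0.02 and a mean of -0.02, and the median was 0.15 with a floor of 5 FPKM and with protein-coding transcripts alone. Fas and Gadd45a, which that list also holds, were the members farthest from 0.

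The 4 genes known to be discussed for Musclin in FAPs were all less than 2-fold apart, with a list median of 0.28 inside the random range. They were chosen from knowledge of the study and are not independent evidence. Cd47, whose product signals against engulfment by phagocytes (ENSMUSG00000055447, chromosome 16, 49855366 to 49915010), was at 28.6 FPKM with Musclin and 18.3 FPKM with vehicle, a log2 ratio of 0.61 and an aligned-base ratio of 1.52 (95% interval 1.43 to 1.61). Filip1l, whose product has been linked to reduced proliferation and migration (ENSMUSG00000043336, chromosome 16, 57353093 to 57573126), was at 16.6 against 12.4 FPKM, a log2 ratio of 0.39 and an aligned-base ratio of 1.39 (1.28 to 1.52). Foxo3, a forkhead transcription factor gene (ENSMUSG00000048756, chromosome 10, 42181841 to 42276755), was at 11.6 against 10.2 FPKM, with an aligned-base ratio of 1.13 (1.05 to 1.21). Npr3 (ENSMUSG00000022206, chromosome 15, 11839896 to 11907287) was at 3.86 against 3.71 FPKM. Its aligned-base ratio of 0.966 (0.853 to 1.09) included 1, so no difference in the gene total was detectable at this depth.

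Transcripts of the study genes Cd47, Filip1l and Npr3 differed in their ratios, and each of these genes has 1 transcript marked significant in the authors' deposited table, higher with Musclin. In Cd47 it is ENSMUST00000230836 (2.12 against 1.01 FPKM), while the main transcript ENSMUST00000084838 (21.8 against 14.5 FPKM) is not marked. In Npr3 it is ENSMUST00000228603, at 0.860 against 0.397 FPKM under the expression floor, with 47 against 22 fragment equivalents, while the main transcript ENSMUST00000066529 was at 2.94 against 3.21 FPKM. In Filip1l it is ENSMUST00000159816, with 5 exons and 4452 bases, at 4.57 FPKM with Musclin and 1.83 FPKM with vehicle, 2.49-fold higher. ENSMUST00000159414, with 2 exons and 3253 bases, starts at 57549242 inside the span of the longer transcript. It was at 12.01 against 10.6 FPKM and is not marked there. The authors' deposited table marks 3033 transcripts of 2335 genes as significant, 1503 higher with Musclin and 1530 lower.

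Of 23 FoxO target genes 2 were 2-fold or more higher and 3 were lower, with a median of -0.15 inside the random range. Bnip3 and Sod2 were the higher members, and Gadd45a and Tsc22d3, which encodes a glucocorticoid-induced leucine zipper protein (5.68 against 12.8 FPKM), were among the lower. Of 15 genes for engulfment signals 3 were 2-fold or more higher, with a median of -0.06 and a mean of 0.17. They were Cd24a (6.03 against 1.17 FPKM), a signal against engulfment, Calr, whose product promotes it at the cell surface, and Thbs1, a CD47 ligand gene (2053 against 990.4 FPKM). Gas6, a bridging ligand gene, was at 125 against 208 FPKM. Of 11 measured genes for natriuretic peptides, their receptors and cyclic GMP signalling, 2 were 2-fold or more lower, with a median of -0.03 inside the random range. Pde5a, a cyclic GMP phosphodiesterase gene, was at 2.75 against 7.61 FPKM and Prkg2, a cyclic GMP-dependent kinase gene, at 7.57 against 11.7 FPKM. The other lower gene, named after its value was seen, was Ostn, listed at 0 with Musclin and at 1.32 FPKM with vehicle (43 fragment equivalents).

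**Figure D3:**
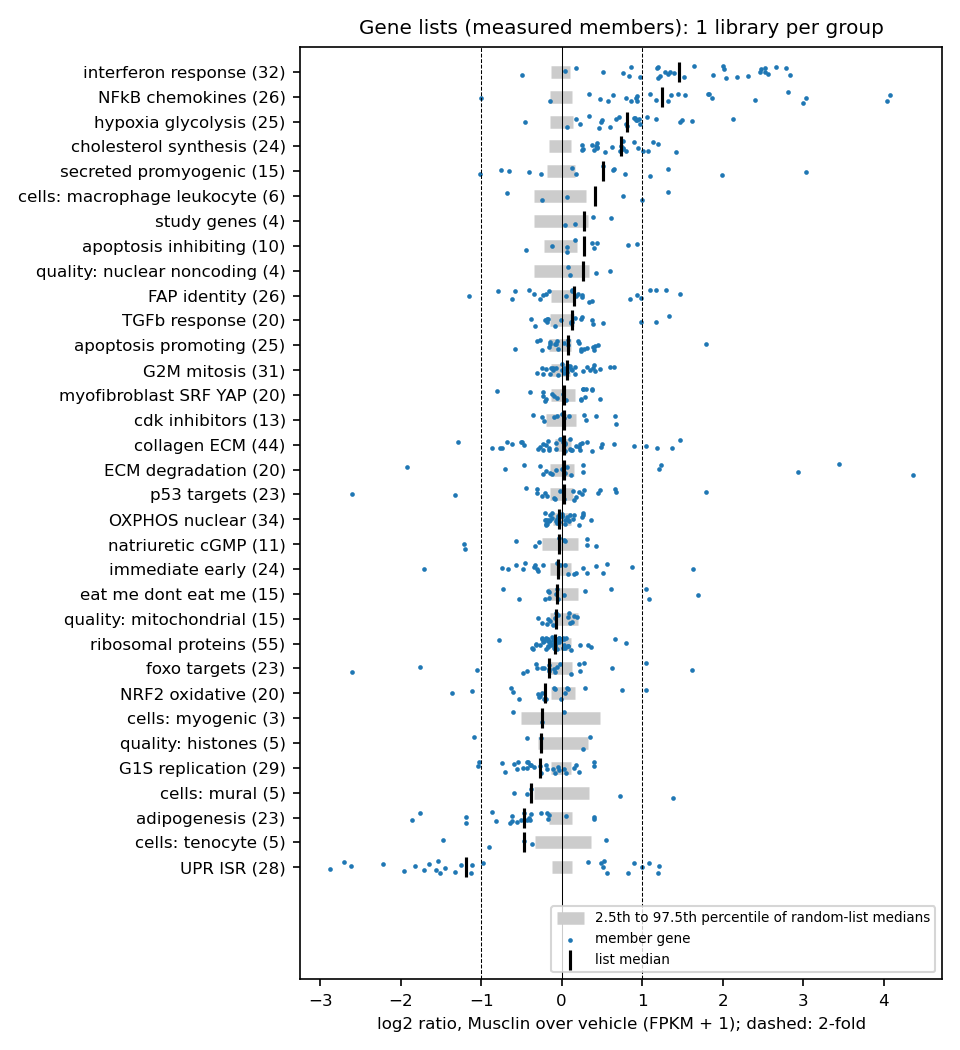
Log2 ratios of Musclin over vehicle (FPKM + 1) for the measured members of 33 gene lists, 1 library per group. Blue points are genes, black marks list medians, grey bars the central 95% of random-list medians, and dashed lines 2-fold. The interferon median (1.46) is the highest and the stress response median (-1.19) the lowest.

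Markers of myofibers, endothelial, Schwann and erythroid cells were mostly under the expression floor, while some leukocyte, mural and tenocyte genes were measured. Among leukocyte markers Cd14 was at 6.87 FPKM with Musclin and 2.95 FPKM with vehicle, and Lyz2, the lysozyme gene, at 8.46 against 14.1 FPKM. The leukocyte median of 0.41 was -0.04 without the expression floor and 0.06 without its largest member. Of 5 measured mural cell genes 1 was 2-fold or more higher, with a median of -0.38 (random range from -0.35) and a mean of 0.14, and the median without the expression floor was -0.06. Ndufa4l2 was at 17.5 against 6.06 FPKM and Cspg4 at 14.0 against 21.5 FPKM. Of 5 measured tenocyte genes 1 was 2-fold lower, Comp at 8.12 against 24.4 FPKM, with a median of -0.47 (random range from -0.33) that was -0.25 without the floor. Of 3 measured myogenic genes none reached 2-fold, with a median of -0.25 inside the random range, and 0.02 without the floor. Only 1 myofiber, 2 endothelial and 2 Schwann cell genes reached the expression floor and none of them was 2-fold apart, and no erythroid gene reached it.

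Among gene groups that reflect RNA composition, none of 55 ribosomal protein genes reached 2-fold, with a median of -0.09 just below a random range that began at -0.07 (-0.06 with the median gene set to 0), and many of these genes share reads with pseudogene copies. None of 34 nuclear-encoded respiratory chain genes and none of 15 mitochondrially encoded genes reached 2-fold, with medians of -0.03 and -0.07 inside the random range. Cytochrome b, encoded by mt-Cytb, was at 3124 against 3714 FPKM. The 4 measured nuclear noncoding RNAs all had FPKM sums higher with Musclin, with a median of 0.26 inside the random range and Malat1 at 95.2 against 89.99 FPKM. Neat1 was at 11.8 against 10.9 FPKM while its aligned-base ratio was 0.745 (95% interval 0.711 to 0.781), so its direction depends on how its transcripts are weighed. Of 5 measured histone genes 1 was 2-fold lower, with a median of -0.26 inside the random range, and 0.10 without the expression floor.

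**Figure D4:**
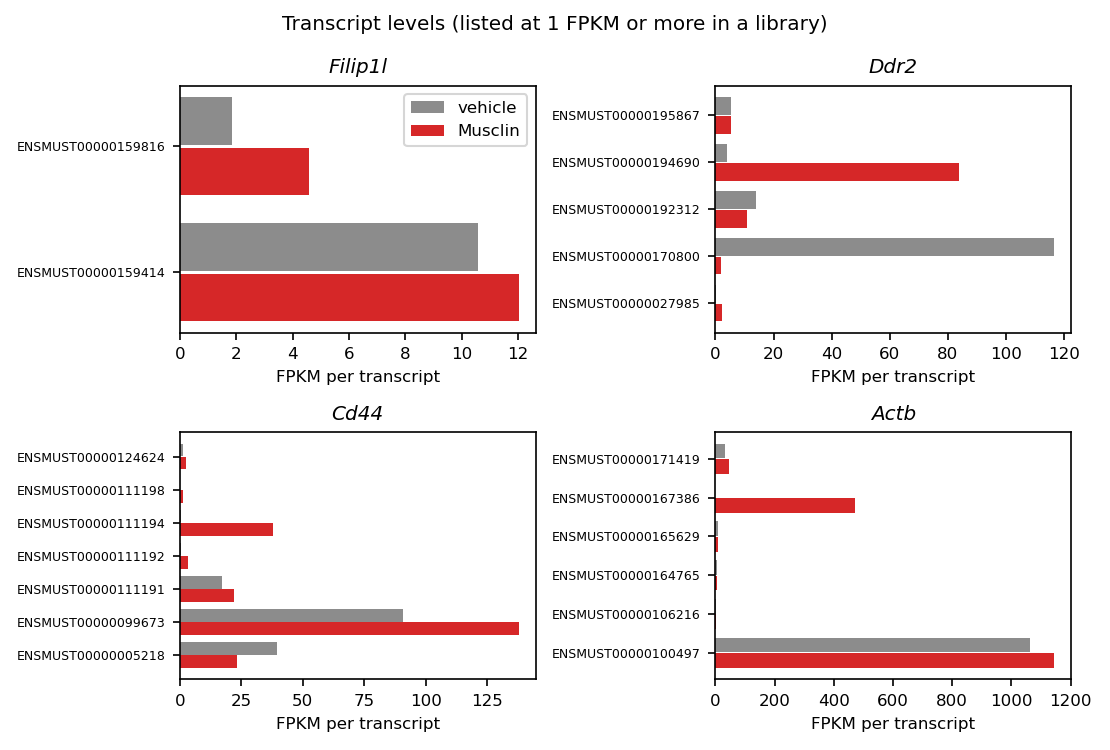
FPKM per transcript in the vehicle (grey) and Musclin (red) libraries for Filip1l, Ddr2, Cd44 and Actb, showing transcripts listed at 1 FPKM or more in a library. The x axis is linear and starts at 0. In Ddr2 the transcript at 117 FPKM with vehicle is at 2.04 FPKM with Musclin, while another goes from 3.97 to 83.8 FPKM.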

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

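The tests on shared exons and on the number of transcripts per gene were fixed before their results were seen, and the transcripts described first were picked after their values were seen. A transcript of Actb (ENSMUST00000167386), which encodes β-actin, was listed at 470 FPKM with Musclin and 0.108 FPKM with vehicle, and it drew attention because its p-value in the authors' deposited table is 1, so the table's significance column leaves it out. The main Actb transcript was at 1144 against 1062 FPKM. Of 128 transcripts with at least 10 FPKM in a library and a difference of at least 10-fold, 81 in 80 genes have a p-value of 1 in the authors' deposited table, 46 higher with Musclin and 35 lower. Among them is the transcript of Mmp10 (23.4 against 0.184 FPKM). A further check took 2614 transcripts at 20 FPKM or more in both libraries. Transcripts with a p-value of 1 or a vanishingly small one were left out. Among the 2614, the p-value in the authors' deposited table followed the absolute distance of the log2 fold from its median almost exactly. The Spearman rho was -0.997 across transcripts, which are not independent replicates.

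The first pattern weighed concerns the 3033 transcripts marked significant in the authors' deposited table. Of these, 2050 (67.6%) belong to genes whose summed FPKM differed by less than 1.5-fold (2178 with the pseudocount). A gene total under 1.5-fold does not reach the 2-fold rule by itself, but it can contribute. Another 21.7% belong to genes 2-fold or more apart, and 302 genes have transcripts marked in both directions. The share of 67.6% is not read as an excess, because most genes differed little. With the pseudocount, the 5th to 95th percentile of log2 ratios over genes at the expression floor ran from -0.59 to 0.62. On that scale 96.8% of genes lay within 2-fold, while 13.75% of marked transcripts belong to genes 2-fold or more apart. In Ddr2, a collagen receptor gene, one transcript was at 2.04 FPKM with Musclin and 117 FPKM with vehicle and another at 83.8 against 3.97 FPKM. Assignment of shared reads between overlapping transcripts is a candidate explanation. In 273 genes, 407 pairs marked in opposite directions shared more exon sequence than other pairs of the same genes. The median Jaccard index was 0.822 against 0.475, a difference of 0.347 (95% bootstrap interval over genes 0.276 to 0.409). The other pairs included transcripts of every type at 1 FPKM or more. A true switch between similar isoforms would give the same overlap, so this test cannot tell the 2 apart. At 5 FPKM or more, 12.6% of transcripts in genes with several transcripts were marked against 7.35% in genes with 1. The ratio of 1.71 lay between the bounds set for and against a different division of reads within genes, so this test did not decide. For marked transcripts in genes less than 1.5-fold apart, a changed share of the gene total follows by arithmetic. What changed that share stays open. A true switch of isoforms with Musclin stays open and was not tested.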

How the results depend on the processing

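No paired analysis was possible because each group has 1 column. For the same reason leaving out columns, count-based and limma tests and a second unit were not run. Using protein-coding transcripts alone, aligned bases per gene and single transcripts were alternatives chosen after seeing the data. With no replicates, a list median counted as moved when it shifted by more than 1 SD of its random-list medians, and a gene when it shifted by more than its counting interval reaches to either side. The list medians outside their random range and the study genes kept their direction in 155 of 157 values, the exceptions being the leukocyte list without the expression floor (-0.043) and Npr3 by aligned bases (-0.04). The other lists and single genes kept theirs in 290 of 294 values, the exceptions being the histone list (0.10 without the floor, 0.0034 with a floor of 5 FPKM and without its largest member) and the myogenic list (0.019 without the floor). Many of these values could hardly change direction. A pseudocount cannot change the sign of a single gene's ratio. The other scalings removed log2 differences of only -0.027 (median gene) and -0.0024 (upper quartile). Single genes other than the study genes were named for their extreme ratios. The counts of kept directions therefore say little about robustness. The cause of the shifts in size was not tested, except that a pseudocount shrinks low genes by construction.

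The counts of genes past 2-fold, 220 higher and 196 lower, were 400 and 360 at a pseudocount of 0.1, 97 and 71 at a pseudocount of 5, and 1416 and 1365 for single transcripts. At a pseudocount of 0.1 medians were 2.09 for interferon, 1.86 for NF-κB, 0.92 for hypoxia, 0.65 for secreted factors and 0.64 for leukocytes. At a pseudocount of 5 they were 0.99, 0.70, 0.21 and 0.14 for interferon, NF-κB, secreted factors and leukocytes, -0.98 for stress, 0.56 for cholesterol and -0.16 for mural genes. Cd47 moved to 0.52 there. All of the 12 highest and 12 lowest named genes except Ccl2 moved too, for example Mmp10 from 4.36 to 2.45 and Avil from -2.86 to -1.28. Over all settings 43 single-gene values moved and 125 did not. Without the expression floor interferon was at 1.34, NF-κB at 1.03, secreted factors at 0.18, apoptosis inhibitors at 0.17, leukocytes at -0.043, mural genes at -0.058 and tenocytes at -0.25. With a floor of 5 FPKM interferon was at 2.005, NF-κB at 1.17, stress at -1.13, hypoxia at 0.90, secreted factors at 0.64 and apoptosis inhibitors at 0.38. Without the largest member interferon was at 1.39, NF-κB at 1.17, stress at -1.13, secreted factors at 0.35, apoptosis inhibitors at 0.17 and leukocytes at 0.061. Interferon was at 1.35 from protein-coding transcripts, and by aligned bases interferon was at 1.65, hypoxia at 0.91 and replication genes at -0.34. Depth limits single low genes, such as those resting on 7 fragment equivalents in a library.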

Other observations

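The tests on leukocytes, scaling, added substances and culture conditions were chosen after the result was seen, while the tests on further ATF4 targets and further folding genes were fixed before their values were seen. Genes for aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, and for amino acid transporters were mostly lower with Musclin. They were tested with other ATF4 targets outside the stress response list, and of these 23 genes together 22 had a log2 ratio below 0. Slc7a1, a cationic amino acid transporter gene, was at 11.4 FPKM with Musclin and 35.3 FPKM with vehicle, and the synthetase genes Wars and Sars were at 30.6 against 82.4 FPKM and 75.3 against 156 FPKM. Slc38a2, another transporter gene, was the exception at 73.8 against 71.6 FPKM. Genes of protein folding and export in the endoplasmic reticulum stood the other way, with 21 of 24 above 0. Pdia3 was at 338 against 207 FPKM, P4hb at 423 against 261 FPKM and Hyou1 at 70.2 against 45.3 FPKM, while Sel1l was at 32.0 against 40.7 FPKM.

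The second pattern weighed is the lower stress response with higher chaperones. Lower endoplasmic reticulum stress as a whole would lower the further folding genes too, but their median log2 ratio was 0.38. It lay above all 10000 random lists, whose range ended at 0.14. Transcripts of these genes were therefore not lower as a group, with 3 of 24 below 0. Higher chaperones were already part of the pattern, so a high median was likely beforehand. The folding genes extend the pattern beyond the list and are not independent of it, so they do not settle the question. The further ATF4 targets had a median of -1.03, against a random range that began at -0.13. They were read in the same libraries as the lower stress response genes, so a low median was likely beforehand. It shows that the lower levels extend beyond the list. A lower ATF4 arm as a whole stays a candidate explanation, which this median restates and does not test. Whether Musclin lowered that arm or the cultures differed in amino acids, oxygen or density cannot be told apart with 1 library per group, where the stress list itself had a median of -1.19.

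The third pattern is the higher interferon and NF-κB lists. A scale factor would shift genes of like expression alike. It is argued against by the median log2 ratio of -0.02 over all genes at the expression floor, beside list medians of 1.46 and 1.25. Rescaling was no further test, because it removed log2 differences of only -0.027 and -0.0024 and could barely move the list medians. With the median gene set to 0 they were 1.48 for interferon and 1.27 for NF-κB. With upper-quartile scaling they were 1.46 and 1.25. The interferon median lay 1.36 above the end of the range of its expression-matched random lists, a value that restates the pattern. More leukocytes as a source of these transcripts stay open, because 18 leukocyte markers outside those lists, 6 of which reached the expression floor, went both ways. The log2 ratio of their summed FPKM was -0.0051, but it was 0.66 without Lyz2, the most abundant, and the sorting markers are not given in the labels. Endotoxin or another substance carried with the recombinant protein could raise the same genes, and with an NF-κB median of 1.25 in the only treated library this cannot be told apart from an effect of Musclin.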
